A study of Trypanosoma brucei brucei with 4 samples.

How the data were processed

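Genomic DNA of Trypanosoma brucei AnTat1.1 was sequenced as 2 input and 2 pull-down libraries, per the labels, after 15 cycles of PCR and as 150-bp paired-end reads. The submitters' processing notes name FastQC 0.11.5, Trimmomatic, BWA 0.7.12-r1039 and MACS2 2.1.1, without their roles or settings. The genome build and the caller's threshold are not given in the sources used here. Each pull-down library has its own list of peaks in the narrowPeak layout, so peaks were called per sample and not on pooled samples. The peak names inside the lists number the pull-downs 2 and 3 where the labels say 1 and 2; the numbers of the labels are used here. Values of the input libraries were not analysed here.

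Each deposited list gives, per peak, a position, a score, a fold at the summit, the −log10 of a p-value and of a q-value, and the summit's offset. The deposited fold is a ratio of pull-down to background, the authors' own value, and was used to describe, rank and filter peaks within a list. The deposited −log10 q had a minimum of 1.31 in replicate 1 and 1.30 in replicate 2, so the lists stop near q = 0.05. The deposited score was 10 times the −log10 q rounded down in 99.9% of the peaks of replicate 1 and 100% of those of replicate 2. Positions are given 1-based.

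Sequences were matched 1 to 1 to chromosomes of the RefSeq gene table of assembly ASM244v1 by their furthest coordinates, which differed by at most 0.852%. The match was checked by rotating summits against the genes of every chromosome (2000 rotations). The genes of a sequence's own chromosome gave the highest z for 9 of 11 chromosomes, and for 8 that z was between 3.95 and 7.77. For chromosomes 1, 6 and 9 it was 0.522, 1.47 and 1.34, so the match of these 3 rests on length alone. The highest z against another chromosome was 2.41. Because the build of the lists is not named, no coordinates of the gene table are printed, and overlap of peaks with genes assumes that both use the same sequences. Chromosome 11 below 300 kb was left out of gene comparisons, with 180 of 10221 genes, because its genes could not be told apart between that chromosome and an unplaced sequence. Of the protein-coding models, 99.9% had a length that is a multiple of 3.

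The summit pileup and the scaled background of each peak were worked out from the deposited fold and −log10 p, taking the fold as (pileup + 1)/(background + 1) and p as the upper tail of a Poisson distribution. The pileup came out whole (within 0.05 of a step) for 100% of peaks. Backgrounds above 150 fragments fell on multiples of 0.790 in replicate 1 and 0.477 in replicate 2, the factor by which the background was scaled. The inverse of the factor, 1.27 and 2.1, is the fold where pull-down and background are both at the ceiling of 2 fragments per position. This step was chosen after the data were seen. Peaks whose pileup exceeded 50% of the ceiling were called near the ceiling, and 80% was tried too.

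The main test was a rotation test, which is a permutation test. All peaks of both lists were shifted together by a random offset on each chromosome, wrapping at its ends, 10000 times with seed 20. The statistic was the mean of the 2 lists, the p two-sided, and the Benjamini-Hochberg method was applied within each family (6 feature classes, 4 distance classes, 11 chromosomes). The smallest p possible is 0.0002. A peak counted for a gene class with an overlap of at least 1 bp, and for intergenic and distance classes by its midpoint. For chromosomes, all were joined into a ring. For the overlap between replicates, replicate 2 was rotated against replicate 1. On simulated data, 100 pairs of rotated lists gave a p at or under 0.05 in 4.83% of 600 class tests, and 0.333% passed after adjustment. With 10% of peaks moved into pseudogenes, that class passed in 20 of 20 simulated pairs. Pseudogenes held a mean of 7.26% of the real peaks against 5.45% under rotation, so the 10% moved is a larger shift. Of 1000 simulated pileups, 100% were recovered exactly. The simulated lists came from the same rotation and the pileups from the same formulas. These checks therefore cover the calculation and not its assumptions.

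Before the data were examined, these alternatives were fixed: peak midpoints, covered length, independent relocation of peaks, rotation of all chromosomes as a ring, the stronger part of each list above its median fold, peaks overlapping the other replicate, an overlap of 50% of both peaks, and leaving out each replicate. Named genes are the 10 with the highest mean, over both lists, of the strongest overlapping peak's fold, among genes with a peak in both. The rule had asked for genes outside families and with a known product, a filter that was not applied because the gene table holds no products. For the same reason, and because it holds no strand and no genome sequence was used here, gene families, genes of thymine modification, strand switch regions, base composition and peak strength by family were not analysed here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.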

Results

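The series mapped 5-hydroxymethyluracil, an oxidised form of thymine, along the genome of Trypanosoma brucei AnTat1.1. In this parasite the base is the precursor of base J, a glucosylated thymine. Genomic DNA was sequenced as 4 libraries with 150-bp paired-end reads: 2 input libraries without enrichment and 2 pull-down libraries captured on streptavidin beads. Values were analysed for the 2 pull-down libraries, each as its own list of peaks, and the input libraries have no values of their own here. Which input, if any, served as the control behind the background of each list is not stated. The total read number of each library is unknown here. The depth behind a peak was read from the list itself, with a median summit pileup of 120 fragments in replicate 1 and 91 in replicate 2. Nothing in the labels says that the replicates came from separate cultures, so their spread may be technical.

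The question of where enriched DNA lies starts with how much of the genome was called. Peaks were narrow and weakly enriched. Replicate 1 held 1570 peaks and replicate 2 held 1457, a mean of 1514 ± 79.9 (SD, n = 2). The median width was 302 bp in replicate 1 and 350 bp in replicate 2, and the peaks covered 550 and 646 kb, or 2.11% and 2.48% of the span of the lists and genes. The fold of pull-down over background at the summit, as the authors' caller gave it, had a median of 1.55 in replicate 1 with a range of 1.18 to 2.56. In replicate 2 the median was 1.71 and the range 1.25 to 3.55. Summit pileups never exceeded 428 fragments in replicate 1 or 456 in replicate 2, which is 2 fragments per position of the smallest peak width of 214 and 228 bp. Peaks above 50% of that ceiling made up 22.3% of replicate 1 (350 peaks) and 16.3% of replicate 2 (238 peaks), and are called peaks near the ceiling here. Both pull-down and background are compressed in such peaks, so their fold is not a free measure of enrichment.

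**Figure D1:**
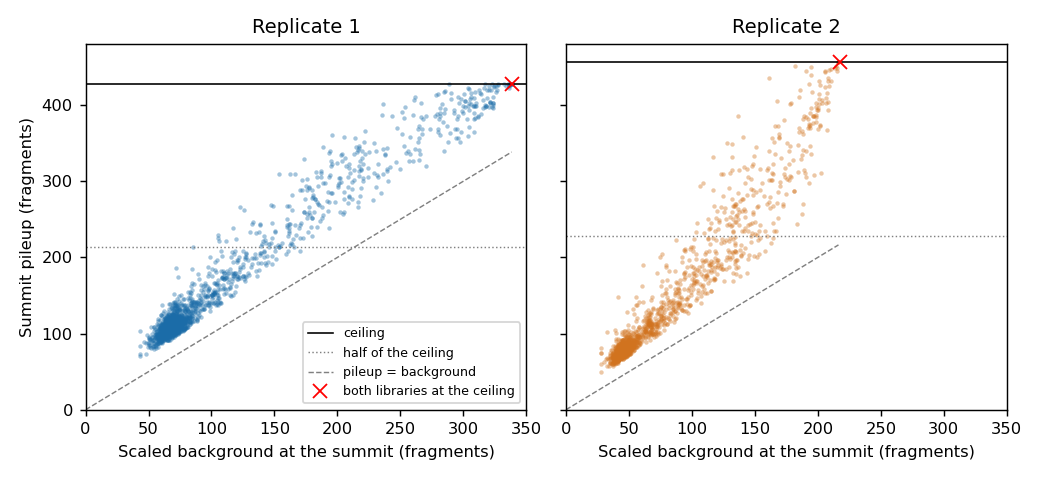
Summit pileup against scaled background, both in fragments, for every peak of replicate 1 (left) and replicate 2 (right). The solid line is the ceiling of 428 or 456 fragments, the dotted line 50% of it, the dashed line equality, and the cross the point where pull-down and background are both at the ceiling, a fold of 1.27 in replicate 1 and 2.1 in replicate 2.

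The replicates marked many of the same places. In replicate 1, 678 of 1570 peaks (43.2%) overlapped a peak of replicate 2 by at least 1 bp, and in replicate 2, 626 of 1457 (43.0%) overlapped a peak of replicate 1. Rotation of the lists against each other gave 4.53% and 4.80%, so the overlap was 9.52 and 8.94 times the chance value (two-sided permutation test by 10000 rotations, p = 0.0002 for both, the smallest they can give). Compared only among themselves, 62.9% and 71.8% of the peaks near the ceiling overlapped, and 29.4% and 29.2% of the other peaks, a difference that was not tested. Most peaks of either list therefore had no partner in the other. Peak strength was weakly related between the lists. Across the 625 peaks matched 1 to 1, Spearman's rho of the fold was 0.14 and Pearson's r 0.23, a description across peaks, which are not independent replicates. Without peaks near the ceiling rho was 0.34 over 355 pairs.

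Peaks lay mainly over protein-coding sequence and were depleted between genes. Sequences of the peak lists were matched to the chromosomes of the ASM244v1 gene table by length, and 10041 genes were used. Peaks overlapping a protein-coding gene made up 69.9% ± 4.26 of a list (SD, n = 2), 1123 peaks in replicate 1 and 946 in replicate 2, against 62.3% under rotation. That is 1.12 times the chance value, and higher than chance in 2 of 2 replicates (1.18 and 1.06 times; permutation test by rotation, adjusted p = 0.0006 over 6 classes). The match of chromosomes 1, 6 and 9 to their genes rests on length alone. Without them, a setting chosen after the data were seen, the value was 1.18 (1.23 and 1.11; permutation test by rotation, adjusted p = 0.0006). The excess therefore came from the other chromosomes, and the reason was not tested. Peaks centred between genes made up 27.9% ± 3.60, against 44.5% under rotation. This was 0.625 times the chance value, at 0.572 in replicate 1 and 0.683 in replicate 2 (permutation test by rotation, adjusted p = 0.0006). The gene models hold coding sequence without untranslated regions, so the space between genes here includes them. Without peaks near the ceiling the protein-coding value was 1.27 and the intergenic value 0.42. Rotation could still place the remaining peaks where those left out lie, which may move both values away from chance. Among peaks shared by both lists no protein-coding excess was seen (0.975 times, permutation test by rotation, adjusted p = 0.618). Among shared peaks that were not near the ceiling it was 1.26 times (permutation test by rotation, adjusted p = 0.0006).

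Pseudogenes were over-represented too. They were overlapped by 106 peaks in replicate 1 and 108 in replicate 2, 1.33 times the chance value (permutation test by rotation, adjusted p = 0.0174). The value passed on replicate 1 alone (1.34 times) but not on replicate 2 alone (1.33) or among shared peaks (1.37; permutation tests by rotation, adjusted p = 0.0228, 0.0559 and 0.169). Of the 836 pseudogenes used, 94 had a peak in replicate 1, 98 in replicate 2 and 51 in both. The pseudogenes with the highest fold among those 51, named after their values were seen, were Tb927.3.320 on chromosome 3 (1.95 in replicate 1 and 2.08 in replicate 2) and Tb11.v4.0042 on chromosome 11 (1.91 and 2.11). The stronger part of each list, above its median fold, held no excess over pseudogenes (0.944 times, permutation test by rotation, adjusted p = 0.938). In settings chosen after the data were seen, the value was 1.44 without peaks near the ceiling and 1.65 among shared peaks not near it. Both passed (permutation tests by rotation, adjusted p = 0.002 and 0.0176). Of 12 alternatives, 9 kept the direction and passed.

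Genes for structural and small RNAs were tested in 3 classes. The 65 tRNA genes and the 6 snRNA genes carried no peak in either list; 1.05 peaks were expected over tRNA genes, so their lack of peaks was within chance (permutation test by rotation, adjusted p = 0.361). Ribosomal RNA genes were overlapped by 12 and 17 peaks, 2.28 times the chance value (permutation test by rotation, adjusted p = 0.0194). This did not pass on replicate 1 alone (1.89 times), by midpoint (2.09), by covered length (1.95), in the stronger part of each list (1.05) or among shared peaks (3.05; permutation tests by rotation, adjusted p = 0.137, 0.0912, 0.166, 0.951 and 0.0624). Small and other non-coding RNA genes were overlapped by 17 and 20 peaks, 3.67 times the chance value (permutation test by rotation, adjusted p = 0.012). Only 3 and 1 peaks were centred in these genes, 1.06 times the chance value, and covered length was at 2.88 times (permutation tests by rotation, adjusted p = 1 and 0.0771). Part of these peaks lay in tandem arrays. On chromosome 9, between positions 2237097 and 2279852 of the lists, 25 peaks in replicate 1 and 29 in replicate 2 lay in a stretch with 28 genes whose locus tags carry the letters SLRNA, of which 8 and 17 had a peak. The median fold of these peaks was 1.26 and 1.96. The match of chromosome 9 to its genes rests on length alone. Without chromosomes 1, 6 and 9, small RNA genes had 7 and 5 peaks, 2.65 times chance (permutation test by rotation, adjusted p = 0.0384). On chromosome 8, between positions 453864 and 459392, all 8 genes of a run of short rRNA genes (Tb927.8.1381 to Tb927.8.1388) had a peak in both lists, with a median fold of 1.27 over 8 peaks and 1.78 over 3 peaks. All peaks of both arrays were near the ceiling. Without such peaks, rRNA genes were at 1.45 times, with 2 and 12 peaks (adjusted p = 0.504), and the small and other RNA genes at 0.926 times the chance value (adjusted p = 1, permutation tests by rotation). The arrays were singled out after the data were seen.

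**Figure D2:**
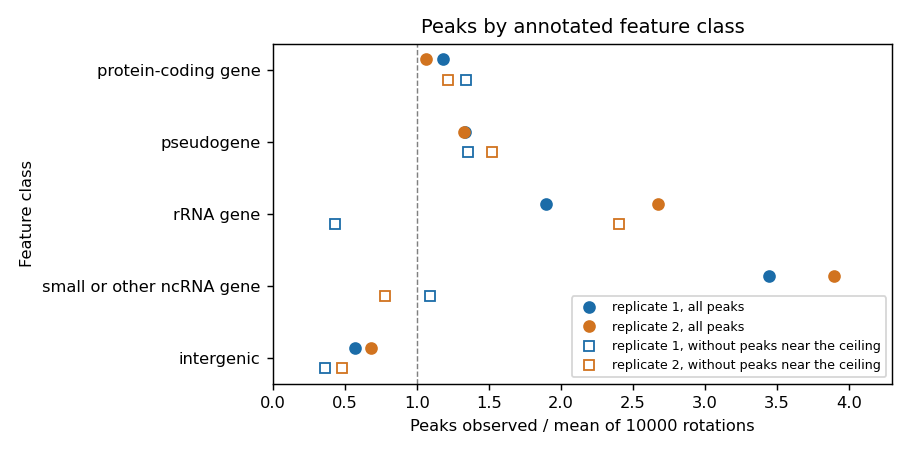
Peaks observed over the mean of 10000 rotations (x axis) for 5 feature classes (y axis); filled circles are all peaks and open squares peaks that are not near the ceiling, blue for replicate 1 and orange for replicate 2. The dashed line at 1 is chance. Protein-coding genes move from 1.12 to 1.27 and small or other non-coding RNA genes from 3.67 to 0.926 as means over the replicates.

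**Figure D3:**
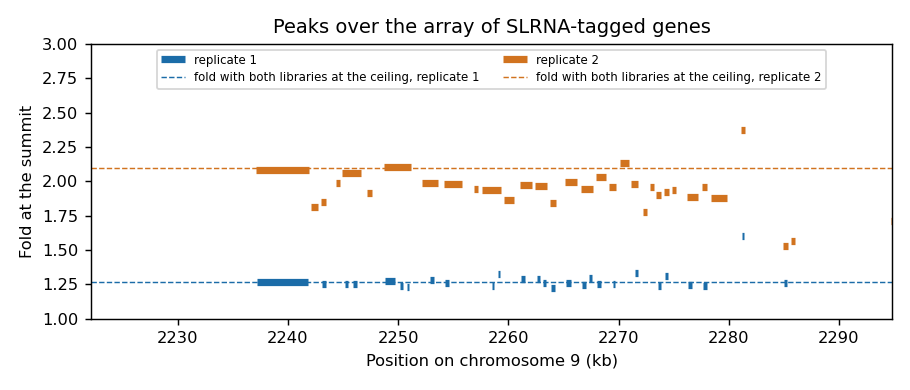
Peaks over the array of SLRNA-tagged genes on chromosome 9, with position in kb on the x axis and the fold at the summit on the y axis (axis starts at 1); each bar spans a peak of replicate 1 (blue) or replicate 2 (orange). Dashed lines show the fold with pull-down and background both at the ceiling, 1.27 and 2.1, near which the medians of 1.26 and 1.96 lie. The match of chromosome 9 to its genes rests on length alone.

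At the level of genes, 463 of 10041 (4.61%) had a peak in both lists, of which 387 were protein-coding. The 10 genes with the highest mean fold were all protein-coding. Their ranking was fixed before the data were examined, but the filter on gene family and product that belonged to the rule was not applied, for lack of products. The highest was TB927.1.1740 on chromosome 1, with a fold of 2.14 in replicate 1 and 3.55 in replicate 2 (mean 2.85 ± 0.993, SD, n = 2). Its strongest peak spanned positions 459209 to 459815 in replicate 1 and 459188 to 460006 in replicate 2, inside the gene model. The match of chromosome 1 to its genes rests on length alone. Tb927.4.5120 on chromosome 4 had a fold of 2.35 at positions 1401816 to 1402150 in replicate 1 and of 2.65 at 1403318 to 1403700 in replicate 2, so its strongest peaks lay in different parts of the gene. Tb927.8.2940 on chromosome 8 gave the closest values of the 10, 2.48 and 2.41, at positions 888599 to 888963 in replicate 1 and 888595 to 888954 in replicate 2, across an edge of the gene model. On chromosome 10, Tb10.406.0560 and Tb10.406.0650, with peaks from positions 2510944 and 2489745, had mean folds of 2.30 ± 0.632 and 2.31 ± 0.195. The neighbouring genes Tb927.7.6580 and Tb927.7.6590 on chromosome 7 had folds of 1.68 and 1.46 in replicate 1 against 2.69 and 3.06 in replicate 2 (means 2.18 ± 0.713 and 2.26 ± 1.13). The 1.46 lies below the median of its list, 1.55, and comes from a peak near the ceiling at positions 1800074 to 1801291, which the 3.06 at 1802162 to 1802522 does not overlap. The rest were Tb927.4.3740 (2.26 ± 0.140), Tb927.8.1210 (2.24 ± 0.295) and Tb10.389.1920 (2.14 ± 0.726). At least 1 peak near the ceiling lay over 6 of the 10 genes. The gene table gives no product for these genes, so none is stated. It gives a symbol of its own to 9 genes, among them the phosphoglycerate kinases PGKA, PGKB and PGKC of glycolysis and the glucose-6-phosphate isomerase PGI. All 9 are on chromosome 1, whose match rests on length alone. Of the 9, 8 had no peak in either list, and trCOIV had a peak in replicate 1 only, with a fold of 1.31. Of all 10041 genes, 1628 had a peak in at least 1 list, so a lack of peaks is common.

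No chromosome stood apart in its peak density at the threshold used. Chromosome 1 had the highest density, 99.6 ± 2.66 peaks per Mb (SD, n = 2), 1.72 times the chance value, with 97.7 in replicate 1 and 101 in replicate 2 (permutation test by rotation of all chromosomes as a ring, p = 0.0142, adjusted p = 0.156 over 11 chromosomes). The other chromosomes ranged from 50.9 ± 1.35 on chromosome 11 to 72.4 ± 0.592 on chromosome 2. Measured as covered length instead, chromosome 1 was at 2.27 times the chance value (permutation test by rotation, adjusted p = 0.0484). Without peaks near the ceiling, a setting chosen after the data were seen, it had 54.0 peaks per Mb, below chromosomes 8 (57.4) and 3 (54.1). That was 1.15 times the chance value, at 0.776 in replicate 1 and 1.53 in replicate 2 (permutation test by rotation, adjusted p = 0.909).

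**Figure D4:**
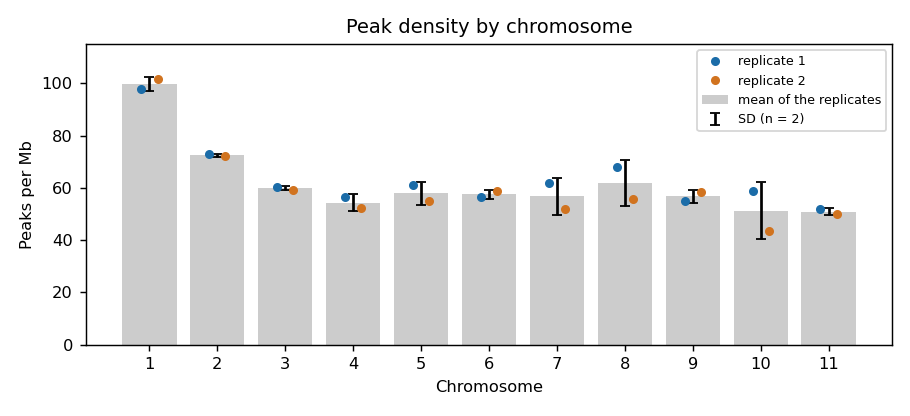
Peaks per Mb (y axis) on the 11 chromosomes (x axis); grey bars are means, error bars the SD (n = 2), and points the replicates. Chromosome 1 is highest at 99.6, and the others lie between 50.9 and 72.4.

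Base J is known from the repeats near telomeres, so peaks were also compared by distance to the chromosome end. None of the 4 distance classes differed from chance in the test over both lists. Within 20 kb of an end there were 24 peaks in replicate 1 and 49 in replicate 2, 1.35 times the chance value as a mean (permutation test by rotation, adjusted p = 0.249). The replicates lay on opposite sides of chance, at 0.861 and 1.86 times. From 20 to 100 kb the value was 1.17, from 100 to 300 kb 1.1 and beyond 300 kb 0.949 (permutation tests by rotation, adjusted p = 0.249, 0.249 and 0.194). The ends were taken from the furthest coordinate in the lists or gene table, so terminal repeats outside these sequences were not assessed.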

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

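The tests in this part were chosen after the results were seen. Only the set of peaks overlapping the other replicate was fixed before.

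Peaks outside the gene comparisons drew attention because they lie in sequence that those comparisons do not use. The unplaced sequence carried 16 peaks in replicate 1 and 29 in replicate 2. Its length is unknown and was taken as 281 kb, the furthest end of a peak on it. That gives at most 57.0 and 103 peaks per Mb, against 60.3 and 55.9 over the whole span. Of these peaks, 9 and 10 were near the ceiling, a larger share than the 22.3% and 16.3% of the whole lists. The first 300 kb of chromosome 11 carried 13 peaks in each replicate, or 43.3 per Mb, of which 4 and 3 were near the ceiling. A count of 0 would allow up to 3 peaks, for counting error only.

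The excess of peaks in protein-coding genes is the first pattern weighed. Peaks near the ceiling did not carry it, since the excess was 1.27 times chance without them, against the 1.12 of all peaks. Rotation could still place the remaining peaks in stretches where the removed ones lie, which may raise this value. The comparison therefore cannot tell whether the ceiling shaped the excess in another way. Whether it comes from calls made in a single replicate cannot be told: peaks overlapping the other replicate gave 0.975 (0.962 in replicate 1 and 0.988 in replicate 2; permutation test by rotation, adjusted p = 0.618), and those of them not near the ceiling gave 1.26. Base composition and the uniqueness of reads in coding against intergenic sequence stay open, as does a real preference of the modified base, and none of these was tested.

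The peaks over the SLRNA-tagged array on chromosome 9 are the second pattern. The match of that chromosome to its genes rests on length alone. In replicate 1 the median fold was 1.05 against a background corrected for the ceiling, down from 1.26. At a Poisson p of 0.001, 0 of 25 peaks stayed above that background. The median pileup of these peaks was already 93.2% of the ceiling, which left little room to pass whatever the enrichment. The ceiling may therefore account for these calls, but the 0 of 25 does not exclude enrichment. In replicate 2 the corrected median was 1.28, down from 1.96, and 23 of 29 peaks stayed above it. The correction assumes evenly spread fragment starts, so in neither replicate can enrichment and the ceiling be told apart. Over the 19 matched peaks of the array, the fold of replicate 2 was 1.56 times that of replicate 1 (95% bootstrap interval 1.52 to 1.58). This compares with 1.66 if both were saturated and 1.08 for matched peaks not near the ceiling. The interval resamples neighbouring peaks, which are not independent replicates, so it describes spread across peaks only.

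The third pattern is an excess of peaks in gene-free intervals of at least 6 kb, 1.55 times chance over both lists (130 and 172 peaks). Without peaks near the ceiling, 25 and 78 peaks remained there and the value turned to 0.676. That is a mean of 0.335 in replicate 1 and 1.00 in replicate 2, so only replicate 1 fell below chance. Rotation could still place the remaining peaks where the removed ones lie, which may lower these values. Among the 87 matched peaks there, outside the SLRNA-tagged array, the fold of replicate 2 was 1.35 times that of replicate 1 (95% bootstrap interval 1.26 to 1.43). Matched peaks near the ceiling in both lists gave 1.42 (1.35 to 1.46), those near it in neither list gave 1.08, and full saturation would give 1.66, so a partly saturated pileup and real enrichment cannot be told apart. Both intervals resample peaks, which are not independent replicates. No biological explanation was tested.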

How the results depend on the processing

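No paired analysis was possible because the input libraries have no values here. Of the planned work, gene families, base composition, strand switch regions and peak strength by family were not run. Alternatives that use the ceiling or leave out chromosomes, those for genes with a peak in both lists and those for the fold of named genes were chosen after the data were seen, and the cause of a change was not tested unless stated. Values below are observed over expected peaks by permutation unless named otherwise. The depletion between genes kept its direction and passed under all 11 alternatives that changed its count or chance value (0.386 to 0.795), and the protein-coding excess under 11 of 12, though with the stronger part of each list its 1.15 is a mean of 1.33 in replicate 1 and 0.951 in replicate 2.

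With the stronger part of each list there were 757 peaks covering 321 kb by construction. Genes with a peak in both lists numbered 155 instead of 463. Pseudogenes turned to 0.944, and rRNA genes were at 1.05 and no longer passed. The rRNA value is a mean of 0 in replicate 1 and 2.18 in replicate 2, and small RNA genes were at 0.818 and 6.01. Peaks near the ceiling had a lower median fold than other peaks in replicate 1 (1.40 against 1.57). In replicate 2 theirs was higher (1.96 against 1.68), so the cut on fold treats them differently in each list. Among peaks overlapping the other replicate, protein-coding genes turned to 0.975, pseudogenes (1.37) and rRNA genes (3.05) no longer passed, and the class beyond 300 kb from an end did (0.891). With midpoints, rRNA genes (2.09) and small RNA genes (1.06) no longer passed, nor with covered length (1.95 and 2.88), under which 1 chromosome passed instead of 0. Independent relocation, which ignores clustering, brought all 4 distance classes past the threshold (1.34, 1.17, 1.1 and 0.949). An overlap of 50% of both peaks gave a rho of 0.26.

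Without peaks near the ceiling there were 1220 peaks covering 427 kb and rho was 0.34; the classes within 20 kb (0.849) and at 20 to 100 kb (0.923) turned below 1, small RNA genes turned to 0.926, rRNA genes were at 1.45, gene-free intervals turned to 0.676 (0.335 in replicate 1, 1.00 in replicate 2), and both tandem arrays had 0 peaks. At 80% of the ceiling, rRNA genes were at 1.62 and small RNA genes at 1.59. Among shared peaks not near the ceiling, rRNA genes turned to 0.897 and small RNA genes were at 1.59.

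Leaving out a replicate gave 0.861 to 1.86 within 20 kb of an end, 0.909 to 0.985 beyond 300 kb, 1.33 to 1.34 for pseudogenes and 1.89 to 2.67 for rRNA genes; the classes within 20 kb and beyond 300 kb passed only on replicate 2 (adjusted p = 0.0444 and 0.0248 by permutation), pseudogenes only on replicate 1 (0.0559 on replicate 2), and rRNA genes only on replicate 2 (0.137 on replicate 1). Neither list reports places under its q threshold, so a place listed in 1 replicate is not shown to differ.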

Other observations

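The gene groups in this part were chosen after the data were seen. Long genes carried more peaks than their length gives by chance. The 44 protein-coding genes of at least 10 kb were overlapped by 70 peaks in replicate 1 and 55 in replicate 2, 1.69 times the value under rotation, which keeps gene lengths (permutation test, adjusted p = 0.0021 over 6 added groups), and 1.75 times without peaks near the ceiling. Peaks were unevenly spread among these genes: 29 had a peak in replicate 1, 25 in replicate 2 and 21 in both lists. The most over a single gene was 11 in replicate 1 and 9 in replicate 2. Across all genes, 11 had at least 3 peaks in both lists, and 6 of them were at least 10 kb long. Of the 11, 8 had a peak near the ceiling in at least 1 list. Tb09.160.1200 on chromosome 9 held the most, 11 peaks in replicate 1 and 9 in replicate 2, with its strongest at positions 543617 to 543837 (fold 2.17) and 530151 to 531103 (fold 1.94). Of its peaks in replicate 1, 10 were near the ceiling. The match of chromosome 9 to its genes rests on length alone. Tb927.2.4230 on chromosome 2 had 8 and 4 peaks, none of them near the ceiling, with a highest fold of 2.02 and 1.65. Tb927.5.1120 on chromosome 5 had 7 in each list, and Tb927.7.3330 and Tb927.7.7400 on chromosome 7 each had 6 and 3. Near the ceiling were 3 and 1 of those over Tb927.5.1120, and 2 and 0 over each of the others.

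Another comparison used only protein-coding genes and pseudogenes, without the shortest of them and without RNA genes. Those with a gene of the same length among the 5 of these types on either side, as tandem copies would have, were also over-represented. Such genes numbered 615 and were overlapped by 127 and 108 peaks, 2.01 times the chance value (permutation test by rotation, adjusted p = 0.0004), and 1.75 times without peaks near the ceiling. Of the 615, 61 had a peak in both lists, and 25 had a peak not near the ceiling in both. The 353 snoRNA genes were at 1.76 times the chance value and did not pass (permutation test by rotation, adjusted p = 0.177). Of these, 6, on chromosomes 10 and 11, had a peak in both lists. Without peaks near the ceiling the value was 1.14, and 1 snoRNA gene had a peak in both lists.

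A gene-free interval on chromosome 1, between positions 160552 and 172994, held 9 peaks in replicate 1 and 6 in replicate 2, all near the ceiling. An interval on chromosome 6, between positions 54645 and 68686, held 4 and 11 peaks, of which 4 and 6 were near the ceiling. The match of chromosomes 1 and 6 to their genes rests on length alone, so whether these intervals are free of genes does too. An interval on chromosome 3, between 875570 and 893350, held 5 and 9, of which 5 and 6 were near it.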
